A study of Drosophila melanogaster with 6 samples.

How the data were processed

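Total RNA of whole 3rd instar larvae was extracted with TRIzol, and libraries were made with a stranded TruSeq kit after removal of ribosomal RNA and sequenced as paired-end reads on a HiSeq instrument, per the labels. The submitters' processing notes name bcl2fastq, TopHat, Partek and the dm6 build; their versions and roles, and the strand setting of the counting, are not given in the sources used here. For each of the 6 libraries the authors deposited 1 table of 34966 RefSeq transcripts. One column holds expected counts, which are estimated reads per transcript shared among isoforms and unscaled for depth, as deposited by the authors. The other holds RPKM values (reads per kilobase of transcript and 1000000 reads) computed by the authors. Of the expected counts, between 29.4% and 32.6% per library were whole numbers within 1e-06. Values of 1000000 or more, at most 7 per library, were written with 3 significant digits. The RPKM values served to check that the counts and the RPKM columns came from the same libraries and were used for no test.

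Transcripts were assigned to genes by RefSeq identifiers with the reference annotation of the Release 6 plus ISO1 MT assembly, the same assembly as dm6. Of the 34966 transcripts 33027 (94.5%) matched a gene and 1939 did not. Counts were summed over the transcripts of each of 16196 genes, 13695 of them protein coding, and rounded to whole numbers. The unmatched transcripts held between 0.0796% and 0.136% of the counts of a library and entered only the test on the transcripts as deposited. Gene symbols and coordinates are those of that annotation. Reads shared among near-identical genes, such as the Hsp70 copies, could not be separated, nor could those of genes that overlap, such as Hsp22 and CG4456 or Corp inside CG1632. The newt transcripts were not analysed here.

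Each genotype, the control and the candidates C1 to C5, had 1 library. Library totals of 75070322 to 86894127 counts on genes were scaled with TMM factors (edgeR 4.0.16 in R 4.3.3, with limma 3.58.1), which were 1.09 in the control and 0.955, 0.890, 0.998, 1.19 and 0.904 in C1 to C5. Genes with a mean CPM of at least 1 over the 6 libraries were measured (11599). A gene counted as higher or lower than the control when its fold was at least 2 and the exact 95% binomial (Clopper-Pearson) interval of the ratio excluded 1. A library with fewer than 3 counts was given a floor of 3 counts for its fold, and a fold against 0 counts is a lower bound. On data simulated with counting noise only, this rule recovered 99% to 100% of changes of absolute log2 ratio 1.5 or 3, with 0 false calls. Changes nearer 2-fold were not simulated.

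Genes that differed from the control in the same direction in all 5 libraries were counted by the same rule. The count was set beside the counts with each other library as the comparator, the product of independent lists, and 20 simulations each with Poisson noise and with the dispersion estimated over the 6 libraries. The control was tested against the 5 transgenic libraries, and each transgenic library against the other 5, with the edgeR quasi-likelihood test (robust fit, 4 residual degrees of freedom with 6 libraries and 3 with 5) and Benjamini-Hochberg adjustment at 0.05. The edgeR fit gives no standard error. The SE written after ± is the absolute log2 fold change divided by the square root of the F statistic of the test. It is approximate and can fall below counting error for genes with few counts in a group. DESeq2 1.42.0 (Wald test, own size factors) was the alternative. The power of the edgeR test was checked on simulated data with 200 changed genes.

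Gene lists for larval tissues, sexes, stages, stress and the processes named in the design (47 lists) were written from general knowledge before the data were examined. A list's median log2 ratio to the control was compared with 10000 random lists of the same size drawn from 20 bins of mean expression, and was called above or below when it left their central 95%. The random lists were drawn from all measured genes, including testis genes nearly absent from C1, C2, C3 and C5. Lists with fewer than 5 measured genes got no percentile. Genes were named by a rule fixed at the same time, among the 9361 genes with a mean CPM of at least 5. It took the 10 higher and 10 lower genes with the largest smallest log2 ratio over the 5 candidates, the 6 highest and 6 lowest log2 ratios per candidate, up to 4 called genes in each direction of the edgeR test per candidate, and w. Up to 4 members of a list per candidate with the largest log2 ratios were named among the measured genes. Other genes in the text, such as kl-5, the Eig71E and Sgs genes in libraries where they were not among those 4, and the genes called after libraries were left out, were chosen after their values were seen.

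Alternatives were DESeq2 size factors, plain CPM, no filter on low counts, a minimum mean CPM of 5, transcripts in place of genes, the DESeq2 test, and leaving out each library in turn. Added after seeing the data were the restriction to the 9933 genes with a mean CPM of at least 1 over C1, C2, C3 and C5, a fit without the control and C4, and list medians without genes under the floor in both libraries. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.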

Results

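Whole Drosophila melanogaster larvae were profiled by RNA sequencing at the 3rd instar, on the 4th day after egg laying. There were 6 libraries, 1 per genotype. The control larvae carried a Tubulin-Gal4 driver over an S-T chromosome. The other 5 libraries came from strains that each misexpressed 1 gene of the newt Notophthalmus viridescens under UAS, called C1 to C5, inserted by phiC31 integrase with a pUAST-attB vector. The libraries held 75131812 (C2) to 86975388 (C1) counts, and 84269592 in the control. Between 13607 (C2) and 15363 (C4) genes had at least 1 count, with 15270 in the control, and 11599 genes had a mean of at least 1 count per 1000000 counts (CPM) over the 6 libraries. The 10 most abundant genes held 14.8% of the counts in the control, between 10.2% (C4) and 19.0% (C2) in the transgenic libraries. With 1 library per genotype no difference between 2 libraries had a replicate check or a p-value. Such differences compare libraries, not conditions, and every interval and floor below covers counting error only.

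The first comparison asked which genes differed between each transgenic library and the control. One difference was in male RNA. Transcripts of testis genes were almost absent from C1, C2, C3 and C5, while C4 held more than the control. betaTub85D, the testis-specific beta tubulin (chromosome 3R, 9408383 to 9410282), stood at 244 CPM in the control, 0.868 in C1, 0.449 in C2, 0.922 in C3, 535 in C4 and 0.667 in C5. S-Lap1, a leucyl aminopeptidase of sperm, stood at 391 CPM in the control and 831 in C4 and at no more than 0.382 elsewhere. loopin-1 of the same family went from 307 CPM in the control to 637 in C4 and to no more than 0.105 in the others. Of 34 measured male germline genes, 33 were at least 2-fold lower than the control in C1, 33 in C2, 32 in C3 and 33 in C5. The median log2 ratios to the control were -8.12, -7.84, -8.01 and -8.01. In C4, 16 of the 34 were at least 2-fold higher and none lower, with a median log2 ratio of 0.99.

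RNA of male somatic cells and of the Y chromosome followed the same split. roX1 and roX2 are noncoding RNAs of the male dosage compensation complex. roX1 stood at 208 CPM in the control and 323 in C4, against 11.9, 16.2, 14.4 and 13.2 in C1, C2, C3 and C5. roX2 stood at 7.34 CPM in the control and 16.8 in C4, and at no more than 0.0449 in the other 4 libraries. The Y-linked dynein heavy chain gene kl-5 (Y, 22250 to 137486) had 3.05 CPM in the control, 7.30 in C4 and 0 counts elsewhere, where the floor of 3 counts lies between 0.0362 and 0.0449 CPM. The Y-linked genes ARY (3.28 CPM in the control, 5.46 in C4) and CCY (2.67 and 4.89) were also at 0 in the other 4. Of 45 Y-linked genes in the gene table, 27 had at least 3 counts in the control, 26 in C4 and 0 in C1, C2, C3 and C5. Most germline genes of both sexes were lower but still present. The RNA helicase gene vas stood at 10.9 CPM in the control, 12.0 in C4 and 2.10 to 2.73 in the other 4, and bru1, a translational repressor of the germline, at 82.5, 158 and 17.5 to 20.02. Of 11 such genes, 7 were at least 2-fold lower in each of C1, C2, C3 and C5 and none in C4, and 1, gcl, was higher in C3 (23.4 to 47.5 CPM). Their medians were -2.04, -1.88, -1.78 and -2.06 in the 4 libraries, and all but that of C3 lay below the central 95% of random lists.

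**Figure D1:**
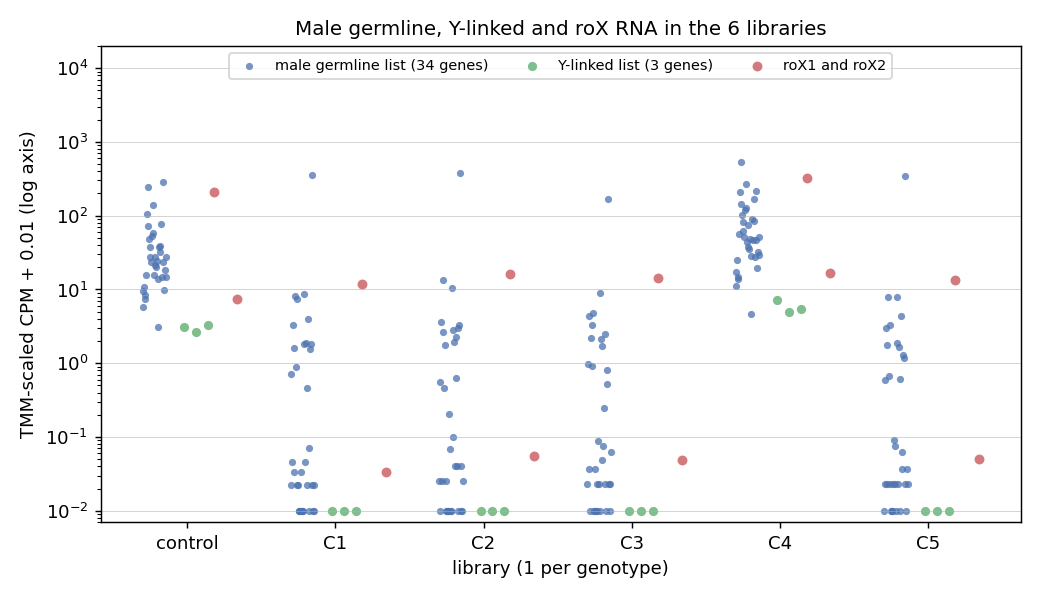
Each point is the TMM-scaled CPM (plus 0.01, log axis) of 1 gene in 1 library, for the 34 male germline genes, 3 Y-linked genes and roX1 and roX2. The Y-linked genes lie at 0 in C1, C2, C3 and C5 and between 2.67 and 7.30 CPM in the control and C4.

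Over all genes with at least 5 CPM in the control, 1127 of 9584 (11.8%) were at 5% of the control level or less in each of C1, C2, C3 and C5. Of these, 977 were autosomal and 150 X-linked, and 21 were on the male germline list. In C4 their median log2 ratio to the control was 0.96 (quartiles 0.83 and 1.07), and 1123 had a ratio above 1. They held 3.14% of the control counts (exact 95% binomial interval 3.14 to 3.14) and 6.78% of the C4 counts (6.77 to 6.78), but between 0.00977% (C5) and 0.0126% (C3) of the others.

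By the size rule, a fold of at least 2 with an interval that excludes 1, C1 had 592 genes higher and 2087 lower than the control. The corresponding numbers were 1037 and 2325 in C2, 698 and 2533 in C3, 1041 and 366 in C4, and 560 and 2156 in C5. At least 8-fold lower were 1652, 1669, 1768, 17 and 1680 genes in the order C1 to C5. Among the 9933 genes with a mean of at least 1 CPM over C1, C2, C3 and C5, a set chosen after seeing the data, the numbers higher and lower were 591 and 455 in C1, 1035 and 689 in C2, 695 and 901 in C3, 380 and 361 in C4, and 560 and 522 in C5. Plain CPM shifted the median log2 ratio of all genes by -0.20 in C1, -0.30 in C2, -0.13 in C3, 0.12 in C4 and -0.28 in C5. The higher genes made up 74.0% of the differences in C4 with TMM scaling and 84.6% with plain CPM.

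**Figure D2:**
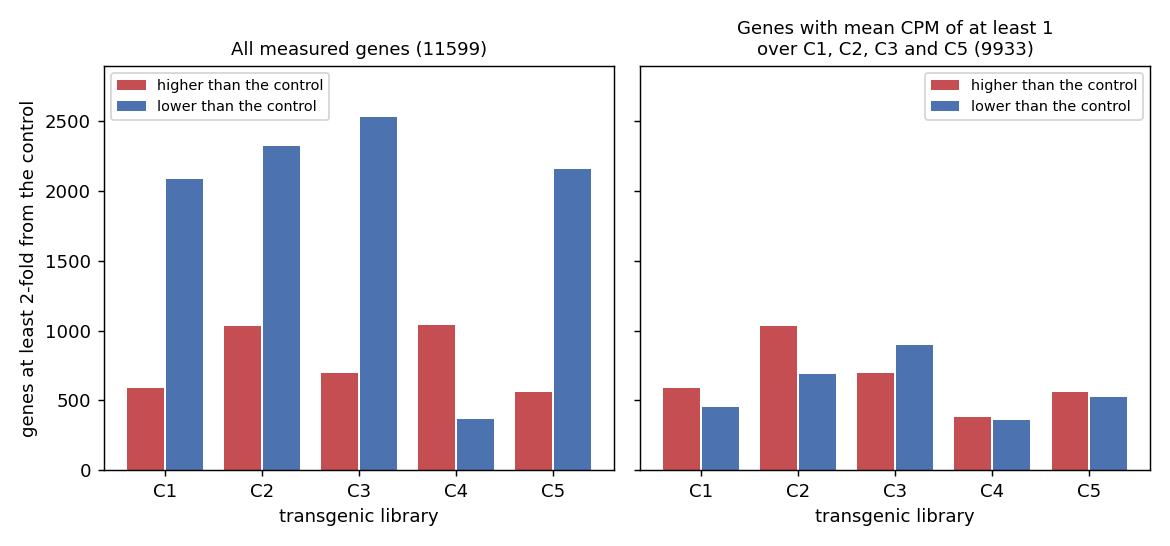
Bars give the number of genes at least 2-fold higher (red) or lower (blue) than the control in each transgenic library, over all 11599 measured genes (left) and the 9933 genes with a mean CPM of at least 1 over C1, C2, C3 and C5 (right). The lower genes of C1 number 2087 on the left and 455 on the right.

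C1 larvae had more RNA of midgut digestive enzymes. Alp8, an alkaline phosphatase gene, went from 2.16 CPM in the control to 74.2 (34.3-fold) and Uro, the urate oxidase of Malpighian tubules, from 0.619 to 19.5 (31.4-fold, log2 interval 4.59 to 5.38). The serine protease gene Jon44E went from 3.38 to 113 CPM (33.5-fold). Of 32 midgut digestive enzyme genes, 21 were at least 2-fold higher in C1 and none lower, with a median log2 ratio of 1.35 that lay above the random lists. This was not particular to C1. The median also lay above in C2 (0.94, 16 genes higher and 2 lower), C3 (0.33, 9 and 9) and C5, and below in C4 (-0.21, 9 and 9). Jon99Fii stood at 7.80 CPM in the control and 135 in C1, and Jon99Ci at 3.00 and 38.5. LysB, a digestive lysozyme, stood at 2.70 and 48.2 CPM. Of the 7 larval serum and storage genes 3 were higher, namely the hexamerin gene Lsp1alpha (2009 to 8114 CPM), Fbp2 (2553 to 9214) and the lipoprotein gene apolpp (628 to 2124). These followed the split in male RNA in part, with apolpp at 514 CPM in C4 and 2124 to 3517 in C1, C2, C3 and C5, and Lsp1alpha at 1765 and 2943 to 12020. Among 18 haemocyte genes 4 were higher, PPO2 and PPO1 (prophenoloxidases of crystal cells, 3.34-fold and 3.25-fold), ItgaPS4 (2.65-fold) and Hml (2.56-fold), and the list median of 0.58 lay above the random lists. The 6 largest decreases were all in genes near 0 in the other libraries without testis RNA: loopin-1, S-Lap4, S-Lap8, S-Lap3, CG12699 and CG3213, the last at 192 CPM in the control.

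C2 larvae had more RNA of muscle, cuticle, salivary glue, glycolysis and detoxification genes. Of 27 muscle genes 20 were at least 2-fold higher and 1 lower, with a median log2 ratio of 1.69. The troponin gene TpnC47D stood at 3.58 CPM in the control and 54.7 in C2 (15.3-fold), and Obsc, the sarcomeric obscurin, at 23.2 and 124. Of 9 larval cuticle genes 7 were higher and 1 lower (median 2.46), with Lcp4 at 1146 CPM in the control and 9159 in C2 and Lcp9 at 6.74 and 184. All 10 salivary glue genes were higher (median 1.43). Sgs3, a glue protein that attaches the puparium, stood at 5560 and 11780 CPM, and ng3 at 2.41 and 177. Of 17 glycolysis and trehalose genes 14 were higher and 1 lower (median 1.21), Gapdh2 from 353 to 1377 CPM and Pglym78 from 131 to 449. Of 31 cytochrome P450 and glutathione S-transferase genes 17 were higher and 1 lower (median 1.04). GstE3 stood at 121 and 857 CPM and GstE7 was 6.33-fold higher at 101 CPM. Each of these 5 medians lay above the random lists.

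In the same library the P450 gene Cyp4p2 went from 0.282 to 74.2 CPM (263-fold, log2 interval 7.49 to 8.65), Uro from 0.619 to 112 CPM (181-fold), CG32198 from 5.72 to 686 CPM (119.8-fold) and CG32241 from 0.217 to 28.3 CPM (130.4-fold). mthl8, a methuselah-like receptor gene, had 0 counts in the control and 9.40 CPM in C2, at least 289-fold higher against the floor of 3 counts (95% log2 limit 7.87). Storage RNA was also higher, with Lsp1beta at 9118 CPM in the control and 28360 in C2 and apolpp at 628 and 3011. Hml, a haemolymph clotting gene of haemocytes, stood at 16.7 and 92.3 CPM, PPO1 at 13.9 and 70.9, and 8 of 18 haemocyte genes were higher with none lower. Ecdysone response genes were split, with 5 of 24 higher and 6 lower, and a median of -0.52 that lay below the random lists. The nuclear receptor genes Hr3 (90.9 to 15.3 CPM), Hr4 (330.2 to 63.2) and Eip78C (321 to 67.8) were lower, and Hr38 (0.597 to 4.80) was higher. ple, the tyrosine hydroxylase, stood at 1384 CPM in the control and 24.2 in C2. The drosomycin-like gene Drsl5 stood at 1227 and 0.748 CPM.

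C3 also differed from the control in salivary gland RNA. The Eig71E genes, a cluster on chromosome 3L that ecdysone induces in late salivary glands, went from low levels in the control to far higher ones. Eig71Ea (15649126 to 15649661) stood at 1.64 CPM in the control and 336 in C3 (205-fold, log2 interval 7.45 to 7.92), Eig71Eb at 0.239 and 105, Eig71Ec at 0.0977 and 100.1, and Eig71Ed at 0.0760 and 74.1. Of 9 measured members 8 were higher and 1, Eig71Ee, lower (5473 to 88.6 CPM). The median log2 ratio was 7.68 and lay above the random lists. Glue genes moved the other way. Of 10, 8 were at least 2-fold lower and none higher, with a median of -4.86, below the random lists. Sgs3 stood at 126 CPM, Sgs4 at 11.7 (1365 in the control) and Sgs5bis at 2.15 (323 in the control). CG32762 (0.206 to 932 CPM) and its neighbour CG4151 (0.402 to 1273 CPM) on the X chromosome were also among the 6 largest increases. CG42717 had 0 counts in the control and 643 CPM in C3, at least 19730-fold higher against the floor (95% log2 limit 13.97).

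Muscle and cuticle RNA were lower in C3. Of 27 muscle genes 16 were lower and 1 higher (Act88F, 1.16 to 9.28 CPM), with a median log2 ratio of -1.42. The myosin heavy chain gene Mhc stood at 496 CPM in the control and 83.8 in C3, and Mlc2 at 815 and 169. Of 9 larval cuticle genes 6 were lower and 1 higher (Cpr97Ea, chosen after its values were seen), Lcp1 at 4888 and 184 CPM and Lcp3 at 403 and 5.41 (median -2.94). Of 18 haemocyte genes 4 were lower and none higher, namely atilla (3.04 to 0.435 CPM), NimC1 (17.6 to 3.99), eater (24.8 to 6.99) and Hml (16.7 to 5.23). These 3 medians lay below the random lists. Of 24 ecdysone response genes 6 were higher in C3, among them ImpL1 (0.891 to 5.44 CPM) and Hr38 (0.597 to 2.70), and the median of 0.37 lay above the random lists. The 3 lower ones were EcR, the ecdysone receptor (99.6 to 22.6 CPM), Eip75B (404 to 128) and Cyp18a1 (13.2 to 2.12). shd, whose enzyme makes 20-hydroxyecdysone, stood at 66.8 and 7.52 CPM. The gluconeogenesis gene Pepck1, with the same coordinates and counts as CG45087, stood at 81.5 and 532 CPM.

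C4 shared the Eig71E pattern with C3 but kept its glue RNA. Eig71Ea stood at 391 CPM, Eig71Ec at 351, Eig71Ed at 284 and Eig71Ef at 178 (0.0217 in the control, a ratio with a log2 interval of 11.1 to 16.05), and 8 of 9 members were higher (median 9.12, above the random lists). Eig71Ee was lower at 1595 CPM. Sgs3 stood at 5157 CPM and Sgs4 at 1114, within 2-fold of the control. Only ng2 (0.0543 to 0.314 CPM) and ng3 (2.41 to 11.6) of the 10 glue genes passed the size rule, and the median was -0.05. CG42713 went from 0.152 to 223 CPM and CG32762 to 439. CG9822 was lower at 1.03 CPM (113 in the control, 109.7-fold lower) and Oatp26F, an organic anion transporter, at 1.10 (19.0 in the control, 17.3-fold lower). Storage protein RNA was lower for Lsp1gamma (17050 to 4821 CPM) and Lsp2 (22200 to 10030), and of 23 lipid metabolism genes only the perilipins Lsd-1 (559 to 251 CPM) and Lsd-2 (266 to 129) passed the rule. Of 31 detoxification genes 6 were lower and 4 higher, with a median of -0.51, below the random lists. The 4 higher ones included Cyp6a23 (2.07 to 12.7 CPM), Cyp9b2 (37.5 to 201) and Cyp6a17 (6.86 to 34.9). Cyp9b2 and Cyp6a17 were at least 2-fold higher than the control in all 5 transgenic libraries.

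**Figure D3:**
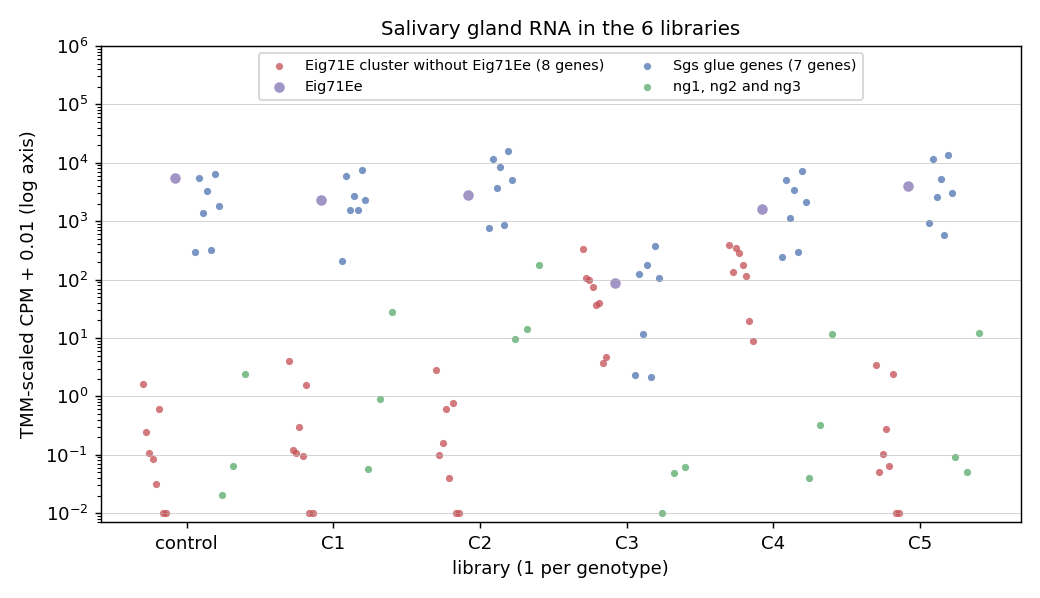
Each point is the TMM-scaled CPM (plus 0.01, log axis) of 1 salivary gland gene in 1 library. The 8 Eig71E genes other than Eig71Ee are high in C3 and C4, where Eig71Ea stood at 336 and 391 CPM, and the 7 Sgs genes are low in C3, where Sgs4 stood at 11.7 CPM.

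C5 stood close to C1. Of 32 midgut enzyme genes 20 were higher and 1 lower (median 1.56), Jon99Fii at 162 CPM and Jon44E at 46.3 (13.7-fold). Of 18 haemocyte genes 6 were higher and none lower (median 0.75), Hml at 70.6 CPM and PPO2 at 96.1. Of 23 lipid genes 6 were higher, among them Lip3 (1.82 to 14.2 CPM), AkhR, the adipokinetic hormone receptor (17.4 to 55.3), and Lsd-1 (559 to 1775), and 2 lower (median 0.54). The glue genes Sgs3 (11670 CPM), Sgs1 (926) and Sgs7 (13460) and ng3 (12.0) were higher and none lower (median 1.01). These 4 medians lay above the random lists. CG12224 went from 1.28 to 109.9 CPM (85.7-fold), CG12057 from 14.8 to 421 (28.4-fold) and CG44624 from 0.163 to 22.7 (139.6-fold). Cyp18a1, which inactivates ecdysteroids, stood at 13.2 CPM in the control and 51.9 in C5. The long noncoding RNA CR43166 went from 1.22 to 35.2 CPM (29.0-fold) and stood at 24.7, 15.9, 33.8 and 1.68 CPM in C1 to C4.

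The immune response, cell cycle, apoptosis and development are processes that the study design names. Antimicrobial peptide RNA was highest in C4, where 15 of 17 genes were at least 2-fold higher and none lower (median log2 ratio 3.51). AttA stood at 9.49 CPM in the control and 182 in C4, Drs at 56.9 and 442, and BomS3 at 0.272 and 37.5. C3 had 7 higher and 5 lower. CecB (0.662 to 29.1 CPM) and CecC (1.56 to 43.4) were higher there and DptB (6.43 to 0.303) lower, and the median of 0.55 turned to -0.03 among genes with a mean CPM of at least 5. In C2, 3 were higher (among them Dro, 0.695 to 19.7 CPM) and 8 lower, among them Mtk (51.7 to 3.07 CPM). C1 had 5 higher and 5 lower. C5 had 2 higher and 5 lower, and its median of -0.55 turned to 0.04 with no filter on low counts. The medians of C3 and C4 lay above the random lists and that of C5 below.

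Among 33 genes of Toll and Imd signalling, 6 were higher and none lower in C1, 7 and 2 in C2, 8 and 1 in C3, 3 and 2 in C4, and 6 and 1 in C5. The medians of C1 (0.53), C3 (0.55) and C5 (0.38) lay above the random lists, as did that of C2 (0.25). Plain CPM, which shifts all C2 ratios alike, turned the C2 median to -0.04, and its place among random lists was not computed anew. PGRP-SB2, a peptidoglycan recognition protein gene, stood at 71.0 CPM in the control, 241 in C1, 0.135 in C2, 2354 in C3, 967 in C4 and 7.08 in C5. In C3 the receptor gene PGRP-LC (41.0 to 151 CPM) and Rel, the NF-kappaB factor of the Imd pathway (134 to 423), were also higher. Of 8 genes of JAK/STAT signalling and the Turandot stress response, upd3 (0.619 to 2.34 CPM), Socs36E (28.8 to 89.8) and dome (68.9 to 141) were higher in C3 (median 0.84), and TotA was higher in C1 (263 to 597) and C2 (642), et in C2 (16.01 to 35.7) and C5 (37.5), and upd1 lower in C1 (4.54 to 2.19). The medians of C3 and C1 (0.50) lay above the random lists.

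Of 45 cell cycle genes, none was at least 2-fold higher in C1, C2, C3 or C5. twe, the Cdc25 phosphatase of male meiosis, was lower in these 4 (15.7 CPM in the control, 1.62, 2.62, 2.17 and 1.76) and higher in C4 (57.2), and aurA (27.2 CPM in the control, 8.60 to 11.2) was lower in the same 4. cid, the centromeric histone gene, was lower in C1 (4.09 to 1.78 CPM) and C3 (2.03). No cell cycle median left the central 95% of random lists. Of 20 apoptosis genes, C3 had 4 higher and none lower, the caspase genes Dronc (93.3 to 280 CPM) and Strica (29.7 to 68.4), the inducer rpr (11.9 to 30.8) and Corp (1.01 to 3.31). The C3 median of 0.40 lay above the random lists. Dronc was also higher in C1 (209 CPM) and rpr in C4 (31.3 CPM), so that rpr was higher in C3 and C4, the 2 libraries with high Eig71E RNA. In C2 Damm was higher (1.26 to 2.69 CPM) and rpr (5.09 CPM) and Buffy (23.9 to 10.9) were lower, and in C5 no apoptosis gene passed the rule. Of 19 genes of JNK signalling and regeneration C3 had 7 higher and 1 lower (chinmo, 51.8 to 15.9 CPM), with a median of 0.62 above the random lists. Gadd45 stood at 15.03 and 76.7 CPM and the matrix metalloproteinase gene Mmp1 at 321 and 952. Ilp8, a relaxin-like peptide gene of discs, stood at 0.445 CPM in the control, 1.79 in C3 and 5.18 in C4.

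No member of the lists for Wnt (24 genes), Notch (22), Hedgehog and BMP (23) or Hippo signalling (15) was 2-fold from the control in any library. Of 17 EGFR pathway genes, aop, a repressor of the pathway, was higher in C3 (143 to 384 CPM) and lower in C2 (53.4), and grk was higher in C2 (9.40 to 22.9). Of 34 Hox and imaginal disc transcription factor genes, sens was higher in C2 (3.32 to 10.8 CPM) and bab2 in C3 (79.4 to 176). The C3 medians were 0.30 for Wnt, 0.37 for Notch, 0.34 for Hedgehog and BMP, 0.40 for EGFR and 0.20 for the disc factors. All 5 lay above the random lists, as did Notch (0.28) and Hedgehog and BMP (0.35) in C1. The disc factor median of C4 was -0.19 and lay below them. The random lists include testis genes nearly absent from C1, C2, C3 and C5, which can lower the random medians there. Percentiles were not computed without those genes. Medians this close to the control therefore do not show that a pathway changed. Over the 40 lists with at least 5 measured genes, 96 of 200 medians lay outside the central 95% of random lists, 64 above and 32 below. The 64 include Eig71E in C2 (median 0.46), which was not called once the 3 genes under the floor of 3 counts in both libraries were left out, a choice made after seeing the data, while Eig71E in C1 (1.31) and C5 (0.71) then lay above. Such a call compares 2 libraries and covers no difference between larvae of the same genotype. Random lists also do not hold genes that vary together, as members of a list may. The central 95% is therefore not an error rate for these calls.

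The median of the heat-shock genes was above the control in all 5 transgenic libraries. Hsp70Bb (Gene ID 48582, chromosome 3R, 12505793 to 12508139) stood at 5.35 CPM in the control and 426, 143, 428, 134 and 111 CPM in C1 to C5. The folds were 79.5, 26.6, 79.9, 24.95 and 20.7, and the 95% log2 interval of the smallest was 4.24 to 4.50. Hsp70Ba stood at 1.36 CPM in the control and 12.3 to 20.2 in the others (9.08-fold to 14.9-fold). Hsp70Bbb and Hsp70Bc stood at 1.727 and 3.649 CPM in the control, 2.225 and 2.028 in C3, and 10.01 to 25.1 in C1, C2, C4 and C5. These Hsp70 genes are near-identical copies, so the split of reads among them is uncertain. Hsp22, a small mitochondrial chaperone, stood at 13.7 CPM in the control, 106 in C2, 150.3 in C4 and 110.0 in C5, but 29.8 in C1 and 20.9 in C3. Hsp68 stood at 212 CPM in the control, 804 in C2, 1135 in C4 and 759 in C5, but 392 in C1 and 234 in C3. Of 16 heat-shock genes 5, 9, 4, 8 and 7 were at least 2-fold higher in C1 to C5 and none lower. Their medians were 0.81, 1.16, 0.60, 1.09 and 0.89, all above the random lists.

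**Figure D4:**
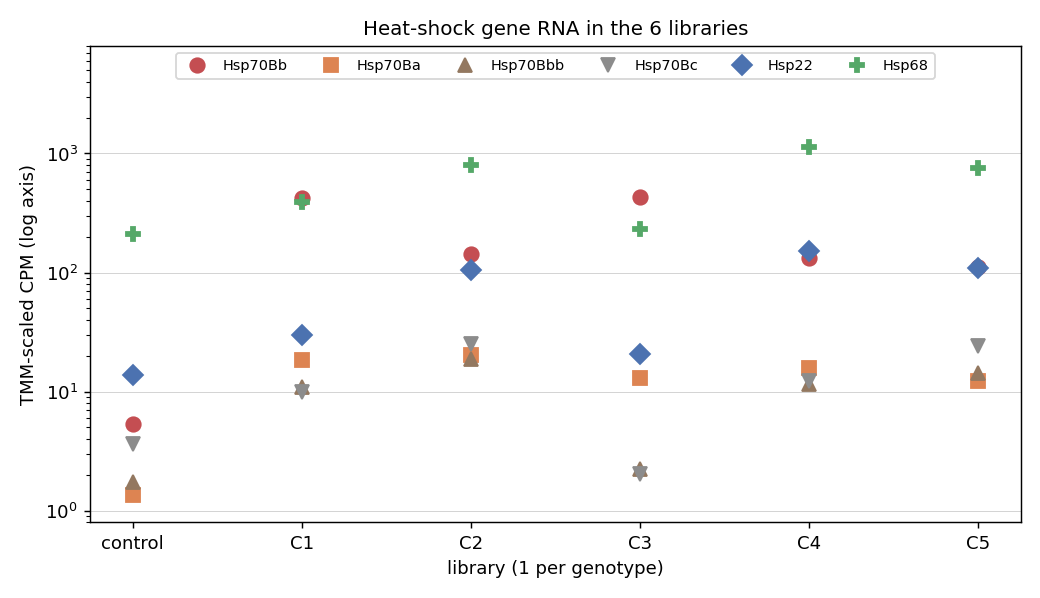
Each marker is the TMM-scaled CPM (log axis) of 1 heat-shock gene in 1 library. Hsp70Bb stood at 5.35 CPM in the control and 111 to 428 CPM in the transgenic libraries, while Hsp22 stood at 20.9 CPM in C3 and 150.3 in C4.

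The second comparison asked which genes differed from the control in the same direction in all 5 transgenic libraries. There were 51 genes higher and 19 lower. sordd2 (X, 15796908 to 15799162) had 0 counts in the control and 5.28, 13.1, 9.39, 4.67 and 7.52 CPM in C1 to C5, at least 143.5-fold higher against the floor of 3 counts (lowest 95% log2 limit 6.86). CG42717 also had 0 counts in the control, and 2.12 and 1.09 CPM in C1 and C2, 138 in C4 and 2.37 in C5. By the smallest ratio of the 5, Hsp70Bb came next, then CG44624 (15.1-fold to 397-fold), Hsp70Ba, Jon44E (6.91-fold to 33.5-fold), CG17633 (4.82 CPM in the control, 25.2 to 60.2 in the others), the metallothionein gene MtnB (1.67 CPM, 6.31 to 25.7), Eig71Ed and Jon65Aii (11.7 CPM, 40.4 to 77.8). Among the genes lower in all 5 were Mipp1, an inositol phosphatase gene (18.8 CPM in the control, 2.17 to 5.33 in the others), p24-2 (26.1 CPM, 5.55 to 7.83), GstE5 (17.5 CPM, 2.09 to 6.39), stj, a calcium channel subunit gene (36.4 CPM, 14.5 to 17.4), and PolQ, the DNA polymerase theta (48.2 CPM, 14.6 to 23.7). CG7272, CG17684, CG9040 and Ugt317A1 were also lower in all 5. CG8568 (31.5 CPM in the control) ranked among the 10 lowest but missed 2-fold in C3 (16.04 CPM).

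These 5 comparisons used 1 control library, and part of any excess may come from it. Independent lists of the same lengths would share 0.01 higher and 0.54 lower genes. Libraries simulated with Poisson noise shared 0 in both directions. Libraries simulated with the dispersion estimated over the 6 libraries shared 409 higher and 322.5 lower on average over 20 simulations, more than observed. That dispersion counts the differences among the 5 transgenic libraries, such as the testis RNA of C4, as noise. Simulations with it therefore cannot tell whether the observed numbers exceed those of unchanged libraries. With another library as the comparator, the others were all higher or all lower than C1 for 6 and 5 genes, than C2 for 122 and 283, than C3 for 368 and 109, than C4 for 69 and 743 and than C5 for 26 and 9. Leaving out C4 raised the shared lower genes to 1897 and the shared higher genes to 108, beside 16.98 and 0.15 for independent lists and 441.4 and 534.1 in the simulation with observed dispersion. Leaving out C3 gave 100 shared higher genes.

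The third comparison set the control against the 5 transgenic libraries as 1 group with the edgeR quasi-likelihood test. No gene passed an adjusted p of 0.05 among 11599, and 117 had an unadjusted p under 0.05. The DESeq2 Wald test called 21 genes higher in the control and 40 lower. The control and C4 both held testis RNA, so 1 library of the group of 5 shared that RNA. Calls made without C4 depend on leaving out that library, the only transgenic one with much testis RNA. Leaving out C4 gave 1605 genes higher in the control and 40 lower at the same threshold. betaTub85D was higher in the control by a log2 fold change of 8.46 ± 0.378 (SE, adjusted p = 0.000753, edgeR), roX1 by 3.97 ± 0.169 (adjusted p = 0.000676) and roX2 by 7.65 ± 0.409 (adjusted p = 0.000872). Most of the tested male germline genes and germline genes of both sexes were higher, while the share of cell cycle genes was below that over all tested genes. The genes lower in the control included sordd2 (0 counts in the control, adjusted p = 0.00379), Hsp70Ba (log2 fold change -3.49 ± 0.433, adjusted p = 0.0071), Jon65Aii (-2.42, adjusted p = 0.0254), apolpp (-2.07 ± 0.395, adjusted p = 0.0319) and Lst, the limostatin gene of corpora cardiaca (-2.64, adjusted p = 0.0379). Hsp70Bb missed the threshold (-5.62, adjusted p = 0.0656).

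In these tests the lone library was assumed to vary as the others do, and different transgenes stood in as replicates. On simulated data with the observed dispersion, the test on 6 libraries recovered 0% to 6.1% of true changes even at 8-fold. For every lone library that dispersion came from the fit of the control against the rest, which counts the testis RNA of C4 as noise. Power with the dispersions of the C1 to C5 fits was not computed. The fit without C4, simulated with its own dispersion, recovered 0%, 7.5% and 36.4% at 2-fold, 4-fold and 8-fold. With a dispersion of 0.05, the 6-library test recovered 92.5% to 98.5% at 4-fold.

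The fourth comparison set each transgenic library against the other 5. The edgeR test called 0 genes for C1, C2, C3, C4 and C5, with 37, 671, 782, 1220 and 43 genes at an unadjusted p under 0.05. The DESeq2 Wald test called 6 genes higher and 522 lower in C1, 394 and 820 in C2, 410 and 974 in C3, 395 and 377 in C4, and 18 and 474 in C5. Without the control library, C4 had 2214 genes higher and 221 lower by edgeR among 11515 tested. Of these, 1587 higher and 17 lower genes were also called in the control when C4 was left out. Independent lists would share 317.8 and 0.8, but both fits used the same 4 other libraries. Each fit also left out the only other library with much testis RNA, so its calls depend on that omission. Nearly all male germline genes tested were higher in C4, while the share of cell cycle genes called higher was near that over all tested genes. CARPB, a carbonic anhydrase-related gene, was lower in C4 (log2 fold change -5.04 ± 0.681, adjusted p = 0.00768), as was apolpp (-2.43 ± 0.401, adjusted p = 0.015). When the other library with Eig71E RNA was left out, edgeR called Eig71Ec alone. The library left out was the only other one with much Eig71Ec RNA, so both adjusted p values depend on that omission. Eig71Ec was higher in C3 (without C4, log2 fold change 9.81 ± 0.271, adjusted p = 0.0216, with 847 genes at an unadjusted p under 0.05) and in C4 (without C3, 11.68 ± 0.281, adjusted p = 0.019, with 824 genes).

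With the control and C4 both left out, a choice made after seeing the data, edgeR tested 9927 genes in the 4 libraries without testis RNA. C4 also held much RNA of the Eig71E genes and of CecB (24.1 CPM, against 29.1 in C3). The C3 calls of these genes therefore depend on leaving out C4. The P450 gene Cyp6a18 stood at 1.66 CPM in C3 and 26.9 to 29.4 in C1, C2 and C5. The control (4.68 CPM) and C4 (10.57 CPM) lay between, so its C3 call depends on leaving out both. Cyp4p2 was higher in C2 (8.94 ± 0.176, adjusted p = 0.0212). In C3 Eig71Ea (6.62, adjusted p = 0.0452), Eig71Eb (10.34, adjusted p = 0.0452), Eig71Ec (9.79, adjusted p = 0.0402), Eig71Ef (9.29, adjusted p = 0.0452) and CecB (7.35, adjusted p = 0.0419) were higher, and the P450 gene Cyp6a18 was lower (-4.07, adjusted p = 0.0452). At an unadjusted p under 0.05 there were 1156 genes in C2 and 1176 in C3. No gene was called by edgeR in C1 or C5, where 61 and 82 genes had an unadjusted p under 0.05, and DESeq2 was not run on these 4 libraries.

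The last comparison counted the genes at least 2-fold apart in each of the 15 pairs of libraries. C1 and C5 were closest, with 491 genes apart, followed by C2 and C5 (1139), C1 and C3 (1221), C1 and C2 (1343), and the control and C4 (1407). The control stood 2679 genes from C1, 3362 from C2, 3231 from C3 and 2716 from C5. C3 and C4 were the farthest pair at 3753 genes. In the set of 9933 genes with a mean of at least 1 CPM over C1, C2, C3 and C5, the distances of the control were 1046 to C1, 1724 to C2, 1596 to C3, 741 to C4 and 1082 to C5. In that set C1 and C5 were 381 genes apart, C2 and C3 2007, and C3 and C4 2106.

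**Figure D5:**
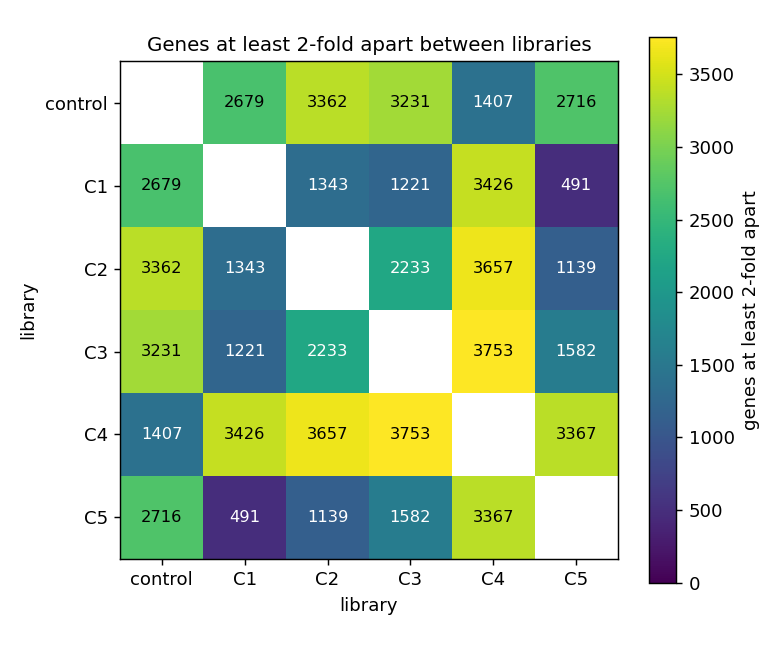
Each cell gives the number of genes at least 2-fold apart between the libraries of its row and column, out of 11599, with colour on a scale from 0. C1 and C5 are 491 genes apart and C3 and C4 3753.

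The vector carries a copy of w, the white gene for an eye pigment transporter. It stood at 53.4 CPM in the control and 65.7, 34.5, 82.3, 61.6 and 73.2 CPM in C1 to C5, and was within 2-fold of the control in each.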

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

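The tests of male RNA, Eig71E RNA and Hsp70Bb in this part were chosen only after the results were seen. Transcripts matched to no gene, which the comparisons of genes leave out, held 0.1358% of the C4 counts (exact 95% binomial interval 0.135 to 0.1366) against 0.1093% in the control, and stood out because they exceeded the control level.

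Testis, Y-linked and roX RNA was nearly absent from C1, C2, C3 and C5. A lower depth of these libraries is argued against, since the smallest of their totals on genes was 0.8918 of the control total, and so is a loss of testis or germ cells from males that were present, since roX2, made in male somatic cells, reached at most 0.6116% of the control. An absence of male larvae from these 4 samples may account for it. roX1 and roX2 reached at most 7.774% of the control there. The ratio of X-linked Lsp1alpha to autosomal Lsp1beta RNA was at least 1.754 times the higher ratio of the control and C4. That ratio did not track the amount of male RNA, however. It was 0.2277 in C4 and 0.2203 in the control, though roX2 in C4 stood at 229.1% of the control. Among the 4 libraries it ran from 0.3994 to 0.5576, so it does not measure the share of males. An effect of the transgenes on the survival or growth of males cannot be told apart from a choice of larvae, because there was 1 library per genotype. The samples' sex is not given in the labels, so the sex composition remains a hypothesis found and tested on the same data.

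Eig71E RNA was high in C3 and C4, with little glue RNA in C3 alone. Carry-over of C4 reads into C3 is argued against, since the testis genes reached a median of 0.1114% of their C4 level in C3 and the 8 Eig71E genes 31.37%. In C4 larvae of a single age past glue synthesis are argued against, since the lowest log2 ratio of the 7 Sgs genes there was -0.293. Older larvae past glue synthesis may account for C3, where the median glue ratio was -4.857, and larvae of mixed ages in C4, with a median glue ratio of -0.047, stay open because the ages within a sample are not in the labels, as does a transgene effect on gland RNA in both.

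Hsp70Bb was higher in all 5 transgenic libraries, with the largest ratios in C1 and C3. In C1 and C3 the highest log2 ratio of Hsp22, Hsp23, Hsp26, Hsp27 and Hsp68 was 1.124 and that of Hsp70Bb at least 6.31. These 5 genes do not decide on heat or another stress as the whole cause there. They leave out Hsp70Ba, at 3.766 in C1 and 3.266 in C3, and Hsp70Bc, at 1.457 and -0.848, whose shared reads are uncertain. Hsp23 and Hsp27 already stood at 4945 and 1829 CPM in the control, which limits their ratios. In C2, C4 and C5 the lowest of the 3 highest ratios of the 5 genes was 2.951, so stress stays open there too. The UAS vector holds hsp70 leader sequence, which could be counted as Hsp70Bb, and a lowest fold of 20.67 does not decide between vector and chromosomal RNA, because the positions of reads were not analysed here. A transgene effect on the chromosomal gene was not tested.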

How the results depend on the processing

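The alternatives were fixed with the main choices, except the restriction to the 9933 genes with a mean CPM of at least 1 over C1, C2, C3 and C5, the fit without the control and C4, and list medians without genes under the floor in both libraries, which were chosen after seeing the data. No paired analysis was possible because all libraries carry the same replicate number, 1 per genotype, so that fewer than 2 numbers are shared. With DESeq2 size factors all 24 counts stayed within 1.5 times their main value. No ratio of a named gene to the control reversed with either scaling. With plain CPM the genes higher in C4 numbered 1580 and those higher in C5 344, as follows from the shift of all ratios. Of the 200 list medians 192 moved with plain CPM and 6 reversed: Toll and Imd signalling in C2 (-0.044), oxidative phosphorylation in C5 (-0.222), cytosolic ribosomal proteins in C2 (-0.018) and C5 (-0.116), and neuron genes in C2 (-0.027) and C4 (0.007). The same shift moves the random lists too, and percentiles were not computed with plain CPM.

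The low-count filter set how many genes were tested. With no filter 3252 genes were lower in C1 and 3331 in C5, 562 lower in C4, 1049 higher in C3 and 1739 higher in C4, and 77 were lower in all 5 libraries. With a mean CPM of at least 5, the lower genes numbered 1165 in C1, 1354 in C2, 1480 in C3 and 1211 in C5, the higher genes of C4 597, and those shared by all 5 libraries 31 higher and 9 lower. In the restricted set of 9933 genes, 455, 689, 901 and 522 genes were lower in C1, C2, C3 and C5 and 380 higher in C4, since the set leaves out genes seen mainly in the control and C4. Transcripts as deposited, more numerous than genes, gave 1684 higher and 3607 lower in C1, 2833 and 4702 in C2, 2571 and 5069 in C3, 2292 and 1284 in C4, and 1568 and 3791 in C5. With no filter the median of antimicrobial peptides in C5 was 0.035 and that of larval cuticle genes in C4 -0.099, and with a mean CPM of at least 5 that of antimicrobial peptides in C3 was -0.026 and of larval cuticle genes in C1 0.034, each reversed; the cause was not tested.

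Leaving out 1 transgenic library at a time gave 58 to 108 genes higher and 22 to 1897 lower in all of the others, with 100 higher without C3, and 108 higher and 1897 lower without C4, where leaving out any other library gave 22 to 28 lower. The 1897 genes include the 1127 near-absent ones, which C4 shares with the control, and only 19 of the 1897 were lower in C4 too. The cause of the change to 108 was not tested. In the edgeR test of the control the leave-one-out counts ran from 0 to 1605 higher and 0 to 40 lower, the highest without C4. For C3 they ran from 0 to 1 higher (Eig71Ec, without C4) and for C4 from 0 to 2214 higher and 0 to 221 lower, the highest without the control, with 1 higher gene (Eig71Ec) without C3. Without the control and C4, edgeR called 1 gene higher in C2 (Cyp4p2), and in C3 5 higher (Eig71Ea, Eig71Eb, Eig71Ec, Eig71Ef and CecB) and 1 lower (Cyp6a18). The DESeq2 Wald test, where edgeR called 0 genes with 37 to 1220 at an unadjusted p under 0.05, called 21 higher and 40 lower in the control, 6 and 522 in C1, 394 and 820 in C2, 410 and 974 in C3, 395 and 377 in C4, and 18 and 474 in C5; the cause was not tested. For C1, C2 and C5 no leave-one-out fit of edgeR called a gene. Depth was not the limit for abundant genes, but genes under the floor of 3 counts in both libraries have no measurable ratio, though the list medians count them at the floor. Without them the Eig71E medians were 1.308 in C1 and 0.711 in C5, both then above the random lists, and 0.47 in C2, then not called, and the glue median in C3 was -5.469, as before below them.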

Other observations

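The genes that set 1 library at least 2-fold apart from each of the other 5 were counted only after the data were seen, by size alone. C4 had 743 genes higher than in every other library, 87 of them among the 9933 genes with a mean CPM of at least 1 over C1, C2, C3 and C5. Osi6, of a family of insect membrane proteins, stood at 58.9 CPM in C4 and at no more than 1.81 in the others, and Rgk1, a small GTPase gene, at 229 CPM in C4 and 39.8 in C3. C2 had 283 genes higher and 122 lower than in every other library. Among them 15 of 27 muscle genes were higher, and nol (142 CPM) and CG11300 (561 CPM) stood at no more than 6.20 and 24.6 elsewhere. CG34193 and Muc68E were lower in C2, at 0.329 and 1.62 CPM, than in any other library, where they stood at no less than 54.6 and 62.0. C3 had 109 genes higher and 368 lower. Tsf3, a transferrin gene, stood at 99.7 CPM in C3 and 8.003 to 17.4 in the others, CG14062 at 419 CPM in C3 and at no more than 24.0, and Listericin, an antibacterial protein gene, at 0.0658 CPM in C3 and 7.28 to 25.6. C5 had 9 higher genes, CG30286, GIIIspla2, CG15044, Cyp18a1, CG9877, CG32302, CG16749, CG4362 and CG11893. It had 26 lower, of which only 11 were among the 9933 genes. S-Lap1, outside that set, stood at 0.06665 CPM in C5 and 0.2245 to 0.3818 in C1 to C3. C1 had 5 higher, CG31157, CG31343 (26.7 CPM against at most 4.94), CG4367, CG16723 and CG13946. It had 6 lower, 3 of them among the 9933 genes, including Reepl1 (4.83 CPM against at least 12.3).

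Several genes outside the male germline list followed the testis RNA. TrxT, a thioredoxin of testis, stood at 73.2 CPM in the control, 155 in C4 and at no more than 0.0667 in the other 4 libraries. RpL10Aa, a paralog of a ribosomal protein gene, stood at 13.9 CPM in the control, 26.1 in C4 and 0 in the others. Of 85 cytosolic ribosomal protein genes only the 4 paralogs RpL10Aa, RpS10a, RpS19b and RpS5b were at least 2-fold lower in C1, C2, C3 and C5. Among the 9933 genes, the X-linked ones had median log2 ratios to the control of 0.21 in C1, 0.16 in C2, 0.13 in C3, -0.10 in C4 and 0.19 in C5. Those of chromosome arm 2L were 0.10, 0.02, 0.05, -0.02 and 0.08. In C1 the medians of 2R, 3L and 3R were 0.126, 0.122 and 0.103. The 83 genes of chromosome 4 had medians of 0.238, 0.019, 0.225, -0.174 and -0.032. The shift in C1, C3 and C4 was therefore not particular to the X. The ratio of Lsp1alpha to Lsp1beta RNA was 0.220 in the control, 0.228 in C4 and 0.399 to 0.558 in the other 4.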
